A study of Mus musculus with 28 samples.

How the data were processed

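Mouse lung cells sorted for EPCAM after removal of cells carrying CD45, CD16/32, Ter119, CD90.2, CD271 or CD31 were profiled by RNA-seq (19 libraries) and ATAC-seq (9 libraries), 28 in all. Recombination was induced at postnatal day 3 and cells were collected at postnatal day 14. In the Yap active line the floxed genes were Stk3 and Stk4, and in the Yap deleted line Yap itself. RNA libraries numbered 6 Yap active, 4 of its controls, 5 Yap deleted and 4 of its controls. ATAC libraries numbered 3, 3, 2 and 1 in the same order, from 50000 cells each. Reads were 150 bp long, with 20 to 30 M planned per RNA library and 50 M per ATAC library. The labels do not say whether each library came from its own animal, so the p-values of single genes measure the spread between these samples. The list tests with a preset correlation, described below, set genes against genes, and Fisher exact tests count genes. Their p-values do not measure that spread.

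The authors' notes name Trim Galore, Bowtie2, Cufflinks, DESeq and HOMER, without versions or the step each served, and genome build mm10. The deposited gene tables hold read counts of 23478 gene rows per line, as their whole numbers show. Neither the counting program nor the gene annotation is given in the sources used here. Spreadsheet software had turned 27 gene names into dates, and 2 names occurred more than once. These rows stayed in the fits under names that cannot be read, and no column of sample values was left unused (0 columns). The authors' region lists name the regions opened or closed in each line with a score and an annotation by HOMER annotatePeaks.pl, per the file headers. The scale of the score is not stated, so scores were used only to rank regions within a list. The authors' 4 peak lists have the broad-peak columns of MACS, in which fold is enrichment over background and the last columns are −log10 p and −log10 q. The version, the cutoff and the libraries pooled for each list are not given.

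RNA libraries held 35.0 to 43.5 M counts in the Yap active table (median 38.1, 17089 to 18087 genes with counts) and 31.9 to 42.9 M in the Yap deleted table (median 37.0, 17418 to 18243 genes). The 10 most abundant genes took 8.34% to 16.6% and 6.89% to 14.0% of counts. No 2 libraries of a group agreed within sampling noise (lowest chi-square per gene 53.1 and 88.3).

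Counts were scaled by TMM, filtered by filterByExpr and compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The change of one line was set against that of the other by the difference of the 2 log2 fold changes in one model. CPM is the count of a gene relative to the TMM-scaled library size, as edgeR gives it. Lists of genes, 32 in number, were fixed before the data were examined. They cover alveolar and other cell types, signalling, metabolism, cell division and stress, and 31 with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The erythroid list had too few measured genes. Each list was also tested with an estimated correlation and with fry, and its genes were adjusted over the list alone. For expression, regions were tied to the gene the authors' annotation gives when its start site lay within 50 kb, while regions of named genes are given at any distance, and peak lists were intersected with bedtools 2.31.1 at an overlap of at least 1 bp.

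Genes are named in the text by rule. The 19 genes named in every comparison comprise the targeted genes, 4 AT1 genes, 3 AT2 genes, 4 transcription factors and genes of the Yap pathway. Beyond them come the called genes with the largest rises and falls, up to 8 per direction and at 4 CPM or more, and list genes called over their list alone. For the difference between lines the 5 smallest p per direction are named. Esr1, Cdkn1a, Gdf15 and other p53 target genes, Trim12a and Pecam1 were looked at per library after the fits.

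Alternatives set before the data were examined were RLE scaling, no count filter beyond 1 count, DESeq2 1.42.0, limma-voom with sample quality weights, leaving out each library in turn, the replicate number as a replicate block, the other list tests, other distance and overlap limits, and the higher-scoring 50% of regions. Chosen after the data were seen were fits without libraries that stand apart, and covariates for the library set or for sex read from Xist. In the Yap active table Xist was high in active libraries 1, 2, 3 and 6 and in control 4 (446 CPM). It was low in active libraries 4 and 5 and in controls 1 to 3, so sex and group are partly confounded there. In the Yap deleted table Xist was high in deleted libraries 1 and 3 and in control 3. A further check divided the same libraries in other ways, 100 per line and 50 for the difference, and repeated the fits. A library was named as standing apart for a gene when Dixon's ratio passed its critical value.

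The fits were tried on simulated tables with 200 genes changed. At a fold of 2, edgeR found 28.3% of them in the Yap active layout, 20.4% in the Yap deleted layout and 20.0% for the difference. At a fold of 4 it found 82.8%, 68.4% and 66.7%. False calls numbered 6, 0 and 7. DESeq2 found more, with 45 and 44 false calls in the layouts of the lines. A simulated AT1 list changed 1.5-fold was found by all 3 list tests with 0 other lists called. Simulated genes varied independently of each other, so this does not give the rate of false list calls in the real libraries. Other divisions of those libraries called a median of 15 lists in the Yap active line and 14 in the Yap deleted line.

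Motif analysis, reads and the signal of single ATAC libraries were not analysed here. Programs drew on Python 3.11.15 and matplotlib 3.10.9 for tables of regions and for figures.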

Results

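Stk3 and Stk4 encode the Hippo kinases MST2 and MST1, which restrain Yap, and their loss is meant to activate it. Reads counted over a whole gene reveal a floxed deletion only in part, since exons outside it are still counted. Stk3 lay at 30.6 to 35.4 CPM in active libraries 2 to 6 but at 49.5 CPM in the library labelled active 1. Control libraries 1 to 3 held 53.5, 50.2 and 54.6 CPM, and the library labelled control 4 held 34.0 CPM. For Stk4, active libraries 2 to 6 lay at 78.5 to 94.1 CPM and active library 1 at 125 CPM, against 103, 106, 112 and 120.0 CPM in controls 1 to 4. Neither passed the test across all libraries (Stk3 log2 fold change −0.42 ± 0.17 SE, Stk4 −0.25 ± 0.13 SE, adjusted p = 0.366 for each). In the other line Yap1, the gene targeted, lay at 78.3, 142, 102, 84.4 and 95.4 CPM in the Yap deleted libraries and at 215, 119, 168 and 187 CPM in their controls (log2 fold change −0.78 ± 0.22 SE, adjusted p = 0.247). The library labelled deleted control 2 thus held less Yap1 than deleted library 2.

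Esr1 supplied a second marker, because the Sftpc-CreERT2 driver carries the hormone-binding part of an estrogen receptor whose reads can be counted at this gene. Whether the receptor part is of human or mouse sequence is not given in the sources used here. Esr1 lay at 211 to 335 CPM in active libraries 2 to 6 and at 242 to 531 CPM in all Yap deleted libraries. In 3 libraries it ran against the label. Active library 1 held 1.97 CPM, active control 2 held 160.0 CPM and deleted control 2 held 87.1 CPM, while the other controls held 0.952 to 3.91 CPM. All libraries were kept in their labelled groups.

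**Figure D1:**
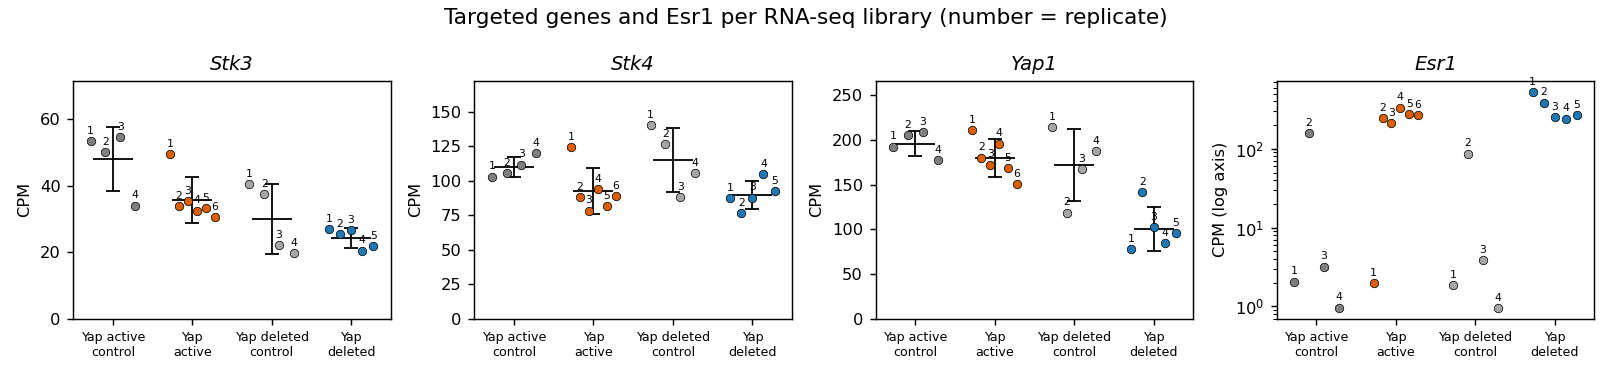
Stk3, Stk4, Yap1 and Esr1 in CPM (log axis for Esr1), with a point per RNA library numbered by replicate, and bars at the group mean ± SD except for Esr1. Active library 1 (Stk3 49.5 CPM, Esr1 1.97 CPM) sits with the controls, and active control 2 (Esr1 160.0 CPM) near the active libraries.

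With Stk3 and Stk4 targeted, dividing-cell, airway secretory and AT2 genes were higher as lists, while endothelial, mesenchymal and mesothelial genes were lower. All of these list calls were lost with an estimated correlation (adjusted p = 0.866 to 0.910 with an estimated correlation). AT1 genes and Yap target genes gave no list call with all libraries, but were called in opposite directions in other fits, given below. No single gene passed the test. AT2 cells make surfactant and give rise to AT1 cells, and Yap is held to favour the AT1 fate. Ager (log2 fold change 0.60), Aqp5 (0.88 ± 0.41 SE), Hopx (0.23) and Pdpn (0.05) of AT1 cells were called neither up nor down. The same held for Sftpc (0.18), Abca3 (0.48) and Lamp3 (0.04) of AT2 cells and for the transcription factors Klf5 (0.72 ± 0.31 SE), Nfib (−0.62 ± 0.29 SE), Nfia (−0.45 ± 0.17 SE) and Nkx2-1 (0.34). Among Yap targets and partners, Ctgf (−0.10), Cyr61 (−0.13), Ajuba (0.30 ± 0.12 SE), Wwtr1 (−0.14) and Tead1 (−0.22) gave no call, and adjusted p ran from 0.366 to 0.941 over these genes. Of 15685 genes edgeR called 0, with 1981 at an unadjusted p under 0.05, while DESeq2 called 11 and limma-voom with sample weights 8871.

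Cell cycle genes rose as a list in the Yap active line, with all 30 higher (median log2 fold change 0.77, adjusted p = 3.3e-09). Club and goblet genes were higher too, all 17 of them (median 0.93, adjusted p = 3.1e-08). Gabrp (0.94) and Scgb3a1 (0.96) of this list rose when adjusted over the list alone. AT2 markers (29 of 30 higher, median 0.36, adjusted p = 0.000215), transitional alveolar markers (18 of 24, median 0.49, adjusted p = 0.000178) and oxidative phosphorylation genes (20 of 21, median 0.38, adjusted p = 0.000141) rose as lists. Upward calls with a larger adjusted p concerned tight junction genes (median 0.20, adjusted p = 0.00177), MHC class II genes (median 0.56, adjusted p = 0.0157) and phospholipid and lamellar body genes (median 0.26, adjusted p = 0.0250). Mesothelial markers (median −1.33, adjusted p = 1.0e-05), endothelial markers (median −1.57, adjusted p = 0.000849) and mesenchymal markers (median −0.46, adjusted p = 0.00704) fell as lists. None of the 11 list calls was kept with an estimated correlation, and those of the phospholipid, MHC class II and mesenchymal lists were lost on leaving out some single library. Direction depended on the fit too. With a covariate for library set the medians of the AT2 (−0.14), MHC class II (−0.32), phospholipid (−0.06) and oxidative phosphorylation lists (−0.05) turned negative. Those of the endothelial (0.10) and mesenchymal lists (0.20) turned positive. With the covariate and without active library 1 and control 2, the cell cycle (−0.35) and MHC class II medians (−0.23) were negative. In that fit the endothelial (0.37) and mesenchymal medians (0.28) were positive. The AT2, transitional, tight junction and phospholipid medians were slightly negative there. Pecam1, an endothelial gene, lay at 14.6 CPM in active library 1 and at 0.937 CPM in control library 4, so the endothelial fall did not hold in every library.

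The remaining 20 lists gave no call in the Yap active line (adjusted p 0.0541 to 0.921). Among them were AT1 markers (21 of 30 higher, median 0.13), the Yap and TEAD target signature (16 of 25 lower, median −0.13), Hippo components (median −0.14) and lung epithelial transcription factors (23 of 30 higher, median 0.23, adjusted p = 0.0541). AT1 markers and Yap targets moved in fits chosen after the data were seen. With a covariate for library set both lists were higher (AT1 median 0.23, adjusted p = 0.00141, Yap median 0.13, adjusted p = 0.00221). Without active library 1 and control 2, Yap targets were lower (−0.31, adjusted p = 0.0235). With the covariate added to that fit, AT1 markers were lower (−0.25, adjusted p = 6.8e-06). None of these calls was kept with an estimated correlation (adjusted p = 0.404 to 0.768). Within 4 lists without a call, genes rose when adjusted over the list alone, namely Nrarp of the Notch list (0.79), Ccnd1 of the FGF and ERK list (0.71), Lcn2 (1.19) and Nfkb2 (0.47) of the inflammatory list, and Lcn2 again of the neutrophil list. Median, mean and test differed in sign for the Notch, FGF and ERK, ciliated, macrophage and lymphocyte lists.

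**Figure D2:**
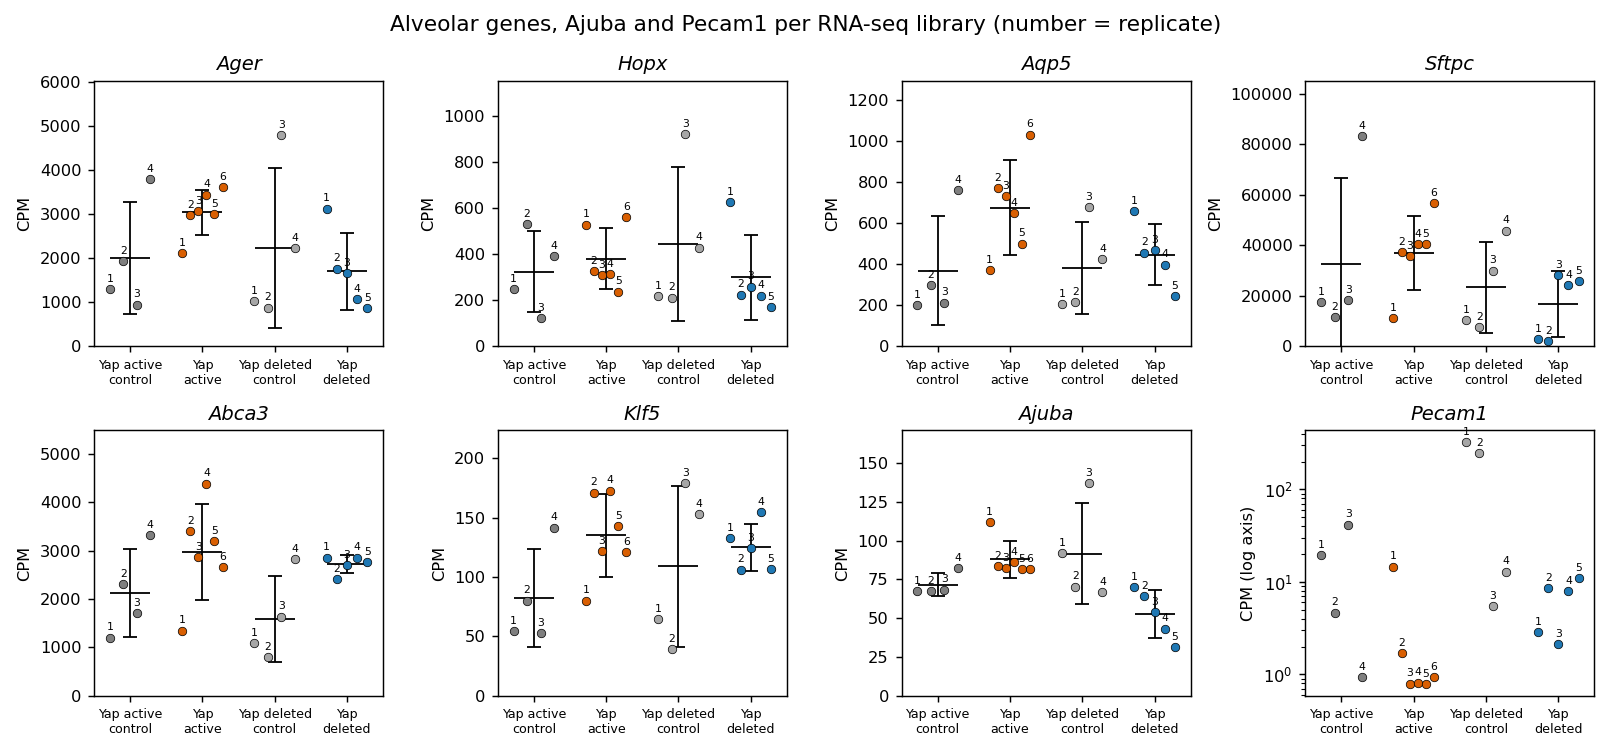
Ager, Hopx, Aqp5, Sftpc, Abca3, Klf5, Ajuba and Pecam1 in CPM (log axis for Pecam1), with a point per RNA library numbered by replicate, and bars at the group mean ± SD except for Pecam1. Deleted controls 1 and 2 hold the most Pecam1 (322 and 245 CPM), and active control 4 the most Sftpc (83336 CPM).

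With Yap deleted, AT1 genes and Yap target genes were lower as lists and AT2 and lipid synthesis genes higher. These list calls too were lost with an estimated correlation (adjusted p = 0.277 to 0.566 with an estimated correlation). Interferon, endothelial and immune lists were lower as well, with calls lost in the same way (adjusted p = 0.277 to 0.383 with an estimated correlation). These genes were high in deleted controls 1 and 2, without which the falls shrank to less than that of the AT1 list except for neutrophil genes, and the AT1 fall needed control 3, where AT1 genes were high. Trim12a alone was called among 15818 genes, and the call did not hold in every fit. The AT1 list had 24 of 30 genes lower (median log2 fold change −0.44, adjusted p = 0.000619), and Cav1 (−1.17) and Ahnak (−1.02) fell when adjusted over the list alone. Control 3 held more of the AT1 genes Ager (4796 CPM), Hopx (919 CPM) and Aqp5 (679 CPM) than the other controls (879 to 2224, 211 to 429 and 206 to 423 CPM), and without it the call was lost (median −0.03, adjusted p = 0.719). Yap and TEAD targets had 23 of 25 genes lower (median −0.46, adjusted p = 7.9e-05), and Hippo components 19 of 25 (median −0.32, adjusted p = 0.000861). AT2 markers had 28 of 30 genes higher (median 0.62, adjusted p = 2.7e-13), with Rab27a (1.05) and Napsa (1.18) up over the list alone. Sterol and fatty acid synthesis genes were higher in 27 of 29 (median 0.59, adjusted p = 8.3e-12), led over the list alone by Elovl1 (1.62) and Dhcr7 (0.77). Phospholipid and lamellar body genes rose as a list (median 0.34, adjusted p = 3.3e-06), with Acot7 (1.48) and Napsa up over the list alone. With an estimated correlation the adjusted p of the AT1 list was 0.566, that of the phospholipid list 0.368, and that of the other 4 lists 0.277. AT2 genes lay lower in deleted controls 1 and 2 than in controls 3 and 4 (median log2 difference −0.91), as did AT1 genes (−1.35), and without these libraries the median was 0.24 for the AT2 list, 0.15 for the sterol list, −0.19 for Yap and TEAD targets, −0.10 for Hippo components and −1.04 for the AT1 list. The phospholipid median shrank to 0.11 and its call was lost (adjusted p = 0.0558).

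Interferon-stimulated genes were lower in all 24 members (median −1.77, adjusted p = 4.1e-15), and 19 of them fell when adjusted over the list alone (adjusted p = 0.277 with an estimated correlation). Endothelial markers fell as a list (median −3.96, adjusted p = 1.1e-12, 14 of 15 genes over the list alone), followed by macrophage (median −2.17, adjusted p = 5.4e-09, 10 genes), neutrophil (median −4.61, adjusted p = 6.3e-05, 9 genes down and 1 up) and lymphocyte markers (median −4.43, adjusted p = 0.000389, 6 of 7 genes). Pecam1 lay at 322 and 245 CPM in deleted controls 1 and 2, at 5.52 and 12.9 CPM in controls 3 and 4, and in every Yap deleted library below control 4. Notch genes fell as a list (median −0.46, adjusted p = 0.000327), with Dll1 (−2.22), Dll4 (−3.04), Mfng (−3.73), Nrarp (−1.15), Lfng and Notch3 lower over the list alone, several of them genes that endothelial cells express. Inflammatory genes (median −0.75, adjusted p = 0.00223, Nfkbia −0.81 over the list alone) and basement membrane genes (median −0.28, adjusted p = 0.0380) fell as lists. Oxidative phosphorylation (median 0.27, adjusted p = 2.3e-05), ciliated (all 16 higher, median 0.64, adjusted p = 0.000166) and FGF and ERK genes (median 0.16, adjusted p = 0.0380) rose as lists. Without deleted controls 1 and 2 the interferon (median −0.30, adjusted p = 0.00333), endothelial (−0.51, adjusted p = 0.00333) and macrophage lists (−0.65, adjusted p = 0.00140) were still lower (adjusted p = 0.493 with an estimated correlation for each), while the lymphocyte (adjusted p = 0.862) and neutrophil calls (adjusted p = 0.0977) were lost. Without these controls the ciliated median turned to −0.14 and the call was lost (adjusted p = 0.0764), and the median was 0.15 for oxidative phosphorylation and 0.29 for FGF and ERK genes. The basement membrane, FGF and ERK and inflammatory calls were lost on leaving out some single library. None of these 11 calls was kept when the correlation was estimated (adjusted p = 0.277 to 0.541 with an estimated correlation).

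Trim12a, an antiviral gene of the Trim cluster on chromosome 7, rose in the Yap deleted line from 0.508 to 0.927 CPM in controls to 4.23 to 4.88 CPM (log2 fold change 2.76 ± 0.26 SE, adjusted p = 0.0243). It has near-identical paralogs, so the assignment of reads within the cluster is uncertain. In the Yap active table Trim12a ran from 0.480 to 12.7 CPM without regard to group. EdgeR called this 1 gene, with 2422 at an unadjusted p under 0.05, while DESeq2 called 871 (167 up and 704 down) and limma-voom with sample weights 0. The Trim12a call was also lost with a replicate block, with sex as a covariate, and on leaving out any one of the 5 deleted libraries or control 3. The AT1 genes Hopx (−0.57), Pdpn (−0.88), Ager (−0.39) and Aqp5 (0.22) were not called, nor were Sftpc (−0.49), Abca3 (0.78 ± 0.34 SE) and Lamp3 (0.31). No call fell on Nfib (−0.54), Nfia (−0.58 ± 0.27 SE), Klf5 (0.20), Nkx2-1 (0.26), Ctgf (−0.47), Cyr61 (−0.27), Ajuba (−0.80 ± 0.28 SE), Wwtr1 (−0.30) or Tead1 (−0.60 ± 0.15 SE), and adjusted p ran from 0.247 to 0.819.

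A further 14 lists gave no call in the Yap deleted line (adjusted p 0.0671 to 0.927), among them cell cycle (24 of 30 lower, median −0.30), club and goblet (median −0.08) and transitional alveolar genes (median 0.00). Without deleted controls 1 and 2 the cell cycle list turned upward (median 0.78, adjusted p = 7.1e-06, and adjusted p = 0.493 with an estimated correlation). Cdkn1a of the transitional list rose over the list alone (2.16), and Fosl2 of the AP-1 list fell (−0.43). Signs of median, mean and test differed for lung epithelial transcription factors, AP-1 factors, club and goblet markers and dissociation genes.

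**Figure D3:**
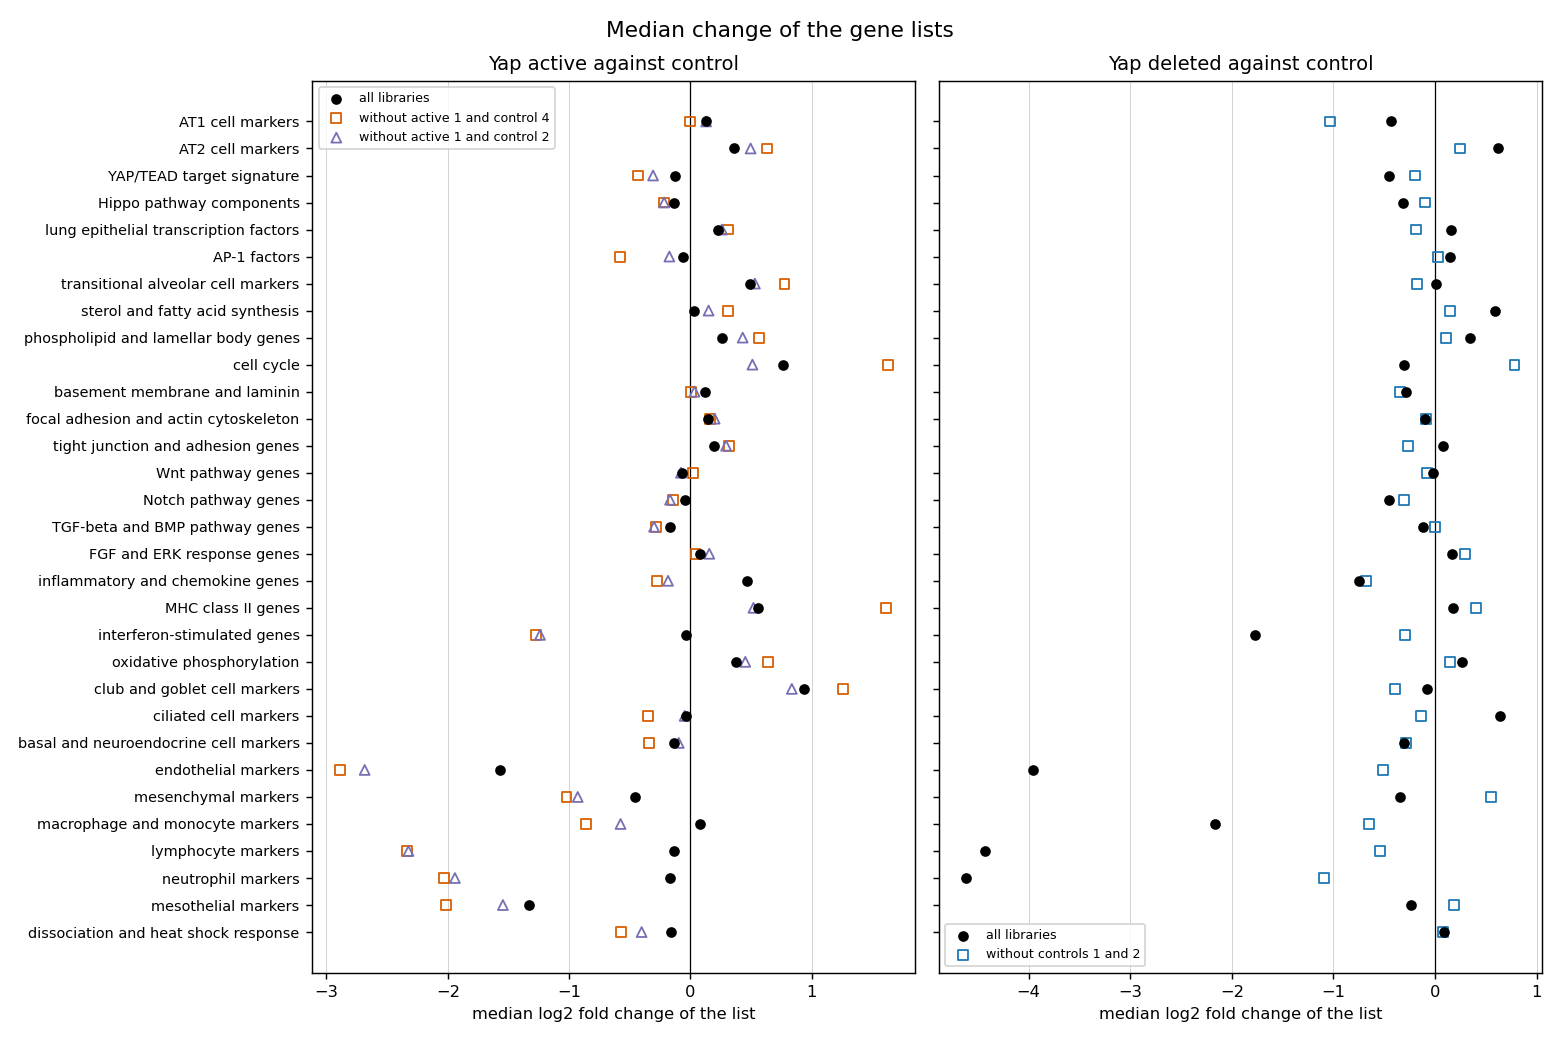
Median log2 fold change of each of 31 lists in the Yap active (left) and Yap deleted (right) lines, with filled points for all libraries and open marks for fits without the libraries named in the key. Without deleted controls 1 and 2 the endothelial median moves from −3.96 to −0.51.

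Between the lines no gene changed differently under edgeR (0 of 16308, with 1055 at an unadjusted p under 0.05), while DESeq2 called 17. Ajuba, a Yap target, leaned higher in the active than in the deleted line (difference 1.10 ± 0.31 SE, adjusted p = 0.696). The smallest p in one direction belonged to Rapgef3 (1.16), Nrarp (1.94), Hmha1 (1.63), Samhd1 (1.83) and Grasp (0.86). In the other direction stood Mitf (−0.88), Sgcb (−0.78), Snhg11 (−1.53), Nrn1 (−1.85) and Hmgcs1 (−0.79), and adjusted p of these 10 genes ran from 0.520 to 0.676. Activation and loss of Yap would move genes in opposite directions, yet the log2 fold changes of the lines correlated positively across genes (0.390). That value comes from fits with all libraries, those that stand apart included. Endothelial markers, for example, fell in both lines (medians −1.57 and −3.96). The correlation therefore cannot be read as an effect of Yap alone. Called genes shared by both lines numbered 0 under edgeR, and under DESeq2 1, P2ry2, up in both, against 0.0897 expected by chance (two-sided Fisher exact test, p = 0.0862).

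Promoters took a larger share of the regions opened in the Yap active line than of the other lists, although most regions of every list lay outside promoters. The authors' lists hold 6017 regions opened and 1392 closed in the Yap active line, and 532 opened and 676 closed in the Yap deleted line. The list of closed active regions ends in 9793 blank lines, so whether it is whole is not known, and its count and shares hold for the regions listed. Promoters made up 29.6% of the opened active regions, against 2.80%, 9.40% and 2.66% of the other lists. Introns held 32.7% and intergenic sequence 26.3% of the opened active regions, and 47.1% lay within 1 kb of a start site. Among closed active regions, introns held 48.1%.

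Opened regions of the Yap active line were common, with 4782 genes named as nearest, and no enrichment of the genes below among them was tested. For Nfib the region covered the promoter (chromosome 4, 82504374 to 82507594, score 115), for Klf5 intron 1 (chromosome 14, 99298610 to 99300208, score 111) and for Nkx2-1 intron 1 (score 58.5). The authors' annotation gave 6 opened regions to Nfia, 3 of them more than 50 kb from its start site. Cyr61 (chromosome 3, 145649356 to 145654144, score 156), Wwtr1 (5' untranslated region, score 135) and Ctgf (60.2 kb upstream, score 64.3), all of the Yap pathway, had opened regions, as had the AT1 genes Aqp5 (score 40.1) and Hopx (score 21.6). Stk3 had an opened region 27.8 kb upstream (score 41.2), and a region in intron 4 of Yap1 was closed (chromosome 9, 7958109 to 7958609, score 12.6). The highest scores went to regions at Hjurp (563), Garem1 (552), Evi5l (496), Sertad2 (459) and Pcmtd1 (454). Closed active regions were led by Ptprs (40.2), BC018473 and 4930404N11Rik. In the Yap deleted line 3100003L05Rik (96.0), Tspan8, C1galt1, Slc35f1 and Cdh11 led the opened regions, and Lrrn3 (266), Gm8579, 4930467K11Rik, 8030451O07Rik and Epha7 the closed ones. None of the 19 genes named throughout had a region in the lists of the deleted line.

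**Figure D4:**
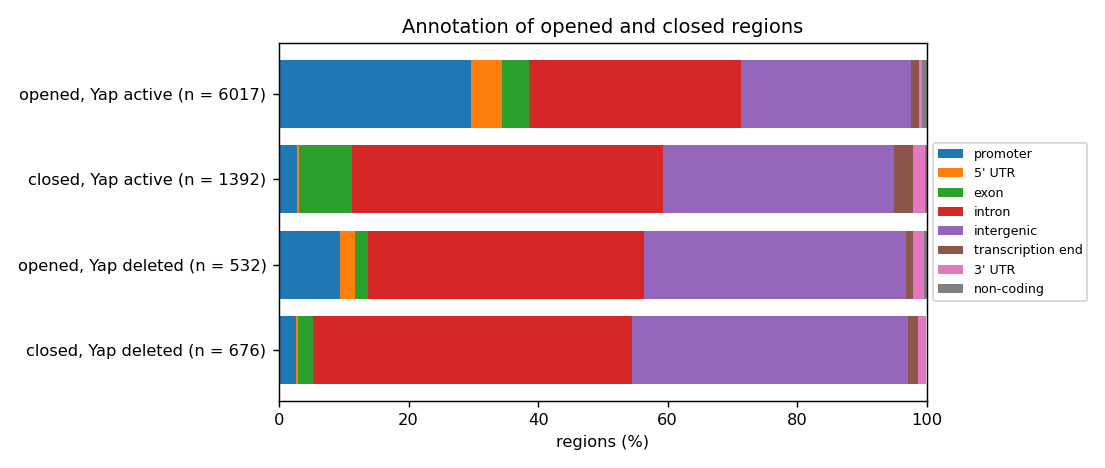
Share of regions (%) by annotation in each of the 4 lists of opened and closed regions, one bar per list. Promoters take 29.6% of the regions opened in the Yap active line and at most 9.40% of the others.

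With all libraries kept, genes near these regions gave no call as a group in expression. Those within 50 kb of regions opened in the Yap active line (3775 genes) had a median log2 fold change of −0.01, and those near closed regions (708 genes) of 0.06. In the Yap deleted line genes near opened regions (280 genes) had a median of −0.10 and those near closed regions (314 genes) of −0.00. Adjusted p of the 4 tests ran from 0.245 to 0.954. Without deleted controls 1 and 2, genes near closed deleted regions were lower with the preset correlation (median −0.08) and not with an estimated one. In that fit the median near opened deleted regions turned to 0.06. Regions opened in the active line overlapped 40 of the regions opened (7.52%) and 54 of those closed (7.99%) in the deleted line. Closed active regions overlapped 0 opened and 2 closed regions of the deleted line.

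The authors' peak lists held 61570 and 53497 peaks for the Yap active line and 344689 and 28399 for its controls. The lowest −log10 p was 2.00 in each list. Only 781, 64, 0 and 31 of these peaks, in the same order, had a −log10 q of at least 1, so most are weak. Shares are of the peaks of the shorter list of each pair. Active lists 1 and 2 shared 15.8%, which is 22.1 times random placement, active list 1 and control list 1 only 0.242% (0.0531 times), and active list 1 and control list 2 15.6% (20.8 times). Active list 2 and control list 1 shared 6.23% (1.48 times), active list 2 and control list 2 0.155% (0.260 times), and the control lists 7.23% (1.64 times). Opened active regions, among them that of Nfib, contained a peak of active list 1 in 93.6% of cases and of control list 1 in 0.216%. Active list 2 reached 33.4% and control list 2 reached 11.6% of them.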

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

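The libraries named here were found by Dixon's ratio within each labelled group after the data were seen, in 14 of 82 groups of libraries, where about 1 in 20 would come by chance. Active library 1 stood apart for Stk3 (ratio 0.748), Stk4 (0.661), Esr1 (0.629), Nfia (0.636, 158 CPM against 91.2 to 116), Cyr61 (0.809, 330 CPM against 75.7 to 124), Ctgf (0.757), Ajuba (0.848) and Tead1 (0.824, 403 CPM against 129 to 178). Active control 4 stood apart for Sftpc (0.909, 83336 CPM against 11639 to 18180), Aqp5 (0.831) and Ajuba (0.939). Esr1 set apart active control 2 (0.986) and deleted control 2 (0.966), and Hopx set apart deleted library 1 (0.804, 626 CPM against 170 to 259). The cause of the Hopx value was not tested.

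The libraries of the Yap active table fell into a set of 6 (active 2 to 6 and control 4) and a set of 4 (active 1 and controls 1 to 3), and the tests of this pattern were chosen after it was seen. An exchange of labels between active 1 and control 4 was excluded by Esr1, which lay at 0.964 CPM in control 4. For an exchange between active 1 and control 2, Esr1 of control 2 (160.0 CPM) would speak in favour, but its Stk4 (106 CPM) lay above the 78.5 to 94.1 CPM of active libraries 2 to 6. Its Stk3 (50.2 CPM) also lay above those libraries, but Stk3 followed the library sets, with control 4 at 34.0 CPM, so this remains open. Another explanation is a difference between sets that needs no change of Yap, such as in cell state or handling. The set contrast in the active table correlated with that between deleted controls 1 and 2 and controls 3 and 4 at 0.516 over 16308 genes, against 0.148 and 0.146 for the other divisions of these controls, which fits that explanation. With only 3 divisions chance cannot be excluded.

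Deleted controls 1 and 2 differed from controls 3 and 4 in 3903 genes by edgeR, with endothelial genes higher (median log2 difference 4.77) and interferon genes too (2.13), and the tests were chosen after this was seen except that of library size. A lower share of alveolar cells alone, with every other cell type raised alike, was excluded, because ciliated markers were lower by a median of −2.34 while endothelial markers were higher. A lower share of all epithelial cells, with the other cell types raised alike, failed the test as set. The medians of 6 lists of other cell types lay 4.40 apart, with lymphocyte (quartiles 4.70 to 5.16) far above mesothelial markers (0.34 to 1.02). The rise of a list also depends on how abundant its genes are without those cells, as for Esam below, so unequal medians cannot exclude equal rises. A lower epithelial share with equal or unequal rises of the other cell types stays open. Medians of AT1 (−1.35), AT2 (−0.91) and ciliated markers (−2.34) were lower, and those of the 6 other lists higher (0.58 to 4.97). Library size was excluded, because control 1 stood apart with 34.4 M counts, within the 33.2 to 42.9 M of the other 7 libraries (control 2 held 31.9 M). Endothelial and immune cells that escaped the negative selection for CD31 and CD45 may be the source, but the test as set could not tell: of its 3 most abundant endothelial genes, Cdh5 (ratio 19.2) and Cldn5 (24.4) passed and Esam failed at 0.880. Esam is abundant in libraries without such cells, so the written consequence of a low value, that these cells are excluded, was wrong. A second form on 3 genes under 50 CPM in the other table gave a lowest ratio of 7.03. It was chosen after the value of 0.880 was seen and does not decide. Of 15 measured endothelial list genes, 13 were at least 4 times as high in both controls as in the highest of the other 7 libraries. This count was not part of the test as set.

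Of the tests on opened regions, that of the peak lists was chosen after the result was seen. Genes with an opened promoter were not higher as a group (median log2 difference −0.0056 from other genes, −0.013 to 0.0018 over 3 fits). A median over 1707 genes cannot exclude higher expression of part of them, and the labels of some libraries are in doubt. Genes with an opened promoter lay at a median expression percentile of 62.4, as a stronger signal at promoters of expressed genes in general would give. The value was not particular to promoters, so it does not decide. Genes near opened active regions lay at 62.7 within 50 kb and at 61.6 at any distance. Those within 50 kb of closed deleted regions lay at 64.8. How the libraries entered the lists was not tested. The peak lists with the same number shared at most 0.260 times as many peaks as random placement, which fits lists called against each other, as when the ATAC library of the other group served as background.

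Sftpc was low against other AT2 genes in some libraries, and an allele effect of the Cre driver, tested after the result was seen, stays open. Sftpc relative to these genes (log2) lay at −0.32 and −0.54 in deleted libraries 1 and 2, but at 2.89 to 3.21 in deleted libraries 3 to 5, among the controls (2.56 to 4.02). These 2 libraries carried the mean difference of −1.66 in the deleted line (two-sided exact permutation test, adjusted p = 0.381) while the active line gave a difference of 0.12, within the spread of the libraries (adjusted p = 0.805, same exact test).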

How the results depend on the processing

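Calls depended on the method and on single libraries, and the fits with covariates or without doubted libraries were chosen after the results were seen. In the Yap active line 0 genes were called in the first fit, 0 to 2 with each library left out, 11 by DESeq2 and 8871 by limma-voom with sample weights (0.183 for active library 1 and 0.200 for control 4). With sex as a covariate 0 genes were called, with 678 at an unadjusted p under 0.05 against 1981 in the first fit. Without active library 1 and control 4 the number was 7232 (3796 up), a circular count because these libraries were picked by their profile. Without active library 1 and control 2, whose Esr1 ran against the labels, 13 genes rose, among them Gdf15, Cdkn1a, Bax, Zmat3 and Aen. Gdf15 and Cdkn1a follow the same split as Esr1, by which these libraries were picked, so for them the calls are circular too. With a covariate for library set added the number was 4. In the Yap deleted line the 1 call on Trim12a was lost with a replicate block (0), with sex as covariate (0) and with limma-voom (0). DESeq2 called 871, and leaving out each library gave 0 to 4, with 0 on leaving out any one of the 5 deleted libraries or control 3. For the difference between the lines, leaving out each library gave 0 to 3 genes, DESeq2 17 and the fit without the 4 libraries that stand apart 3914, again circular. Genes shared by both lines rose from 0 to 1 with DESeq2. All lists called with the preset correlation (11 and 17) were lost with an estimated one (0 and 0) and with fry (0 and 0), while a covariate for library set gave 18 in the Yap active line. That covariate turned the medians of the AT2 (−0.14), MHC class II (−0.32), phospholipid (−0.06) and oxidative phosphorylation lists (−0.05) negative. It turned those of the endothelial (0.10) and mesenchymal lists (0.20) positive. The fit without active library 1 and control 2 with the covariate reversed the cell cycle (−0.35), MHC class II (−0.23), endothelial (0.37) and mesenchymal lists (0.28). The AT2, transitional, tight junction and phospholipid medians were slightly negative in that fit. Without deleted controls 1 and 2 the AT1 list fell further (median −1.04, adjusted p = 2.6e-24, and adjusted p = 0.327 with an estimated correlation), while the interferon list shrank to −0.30, the endothelial list to −0.51 and Yap targets to −0.19. The replicate block used libraries whose number occurs in both groups, although the labels do not say that a shared number means a shared origin. Libraries of one number shared deviations with correlations of 0.0091 to 0.52 in the Yap active line and −0.25 to 0.44 in the Yap deleted line, where numbers 2, 3 and 4 correlated best with their own number and number 1 did not. With the block edgeR called 0 genes in each line. An overlap of at least 50% of both peaks left 8.88%, 0.0845%, 7.68%, 1.45%, 0.0634% and 2.08% of the peaks of the shorter list shared in the order active 1 and 2, active 1 and control 1, active 1 and control 2, active 2 and control 1, active 2 and control 2, and the controls. Only 2, 1, 0 and 0 peaks of the 4 lists had the authors' q below 1e-05. In the higher-scoring 50% of regions promoters made up 46.8% of the opened active and 0.888% of the closed deleted regions. Median log2 fold changes of genes near regions were −0.0016 within 10 kb of opened active regions and −0.013 at any distance from closed deleted regions. They lay further from zero within 10 kb of closed active (0.11) and opened deleted regions (−0.16). Without active library 1 and control 4, 30.5% of genes within 50 kb of closed active regions rose and 12.8% fell. Other genes gave 23.8% and 22.2%, and these counts are circular as above. Near opened active regions 23.0% rose and 23.3% fell, against 24.4% and 21.3% of other genes. Without deleted controls 1 and 2 the medians near opened and closed deleted regions were 0.062 and −0.082. The last passed with the preset correlation, not with an estimated one.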

Other observations

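Some targets of p53 were high in the libraries where Esr1 reads, taken as a sign of the Cre driver, were high, and this was tested after it was seen. Cdkn1a lay at 313 to 635 CPM in active libraries 2 to 6 and at 300 CPM in active control 2, but at 49.1 to 68.7 CPM in the other active controls and at 60.4 CPM in active library 1. Gdf15 followed the same split, with 33.2 to 70.3 CPM in active libraries 2 to 6 and 34.0 CPM in active control 2, against 2.44 to 4.57 CPM in the other controls and 4.03 CPM in active library 1. In the Yap deleted line Cdkn1a lay at 346 to 807 CPM in deleted libraries, at 242 CPM in deleted control 2 and at 50.6 to 99.1 CPM in the other controls. Of the p53 list 17 of 24 genes were higher in the Yap active line and 21 of 25 in the Yap deleted line (medians 0.56 and 0.61). With an estimated correlation an unadjusted camera test gave 0.117 and 0.0251. Sesn1 ran the other way, at 13.7 to 18.5 CPM in active libraries 2 to 6 and 19.9 to 31.8 CPM in the active controls. In the deleted line 17 target genes not used to find the pattern gave an adjusted p of 0.0476 in a two-sided exact permutation test of the labelled groups, while 16 such genes gave 0.362 in the Yap active line. A p53 response of cells that carry an active recombinase may explain this, but the list and the groups come from the same data, and no Cre-only library was analysed here.

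Trim12a, the gene called in the Yap deleted line, may mark a chromosome 7 segment of other strain origin rather than Yap. Of 6 measured genes within 1 Mb, 4 had an unadjusted p under 0.05 (66.7%, against 15.3% elsewhere, two-sided Fisher exact p = 0.00633). All 6 are Trim paralogs that can share reads, among them Trim30a (−3.47), Trim12c (−1.57), Trim34b (−1.39) and Trim30d (1.84), so they are not independent and the test leaves shared reads open.

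How far the numbers of calls stand above chance was tested with the same libraries divided in other ways, for genes after the calls were counted. In the Yap active line 85 of 100 divisions called as many lists as the labelled groups (11 lists, highest other 22), so chance cannot be excluded. For the Yap deleted line 4 of 100 divisions, the labelled one among them, called as many genes (1 gene, Trim12a, highest other 548). Few divisions reached this count, but it is a single gene and the test was set after it was known. Chance therefore cannot be excluded here either. The call was also lost on leaving out any one of the deleted libraries or control 3. For its lists 30 of 100 divisions called as many (17 lists, highest other 20), and chance cannot be excluded. Where edgeR called 0 genes (1981 and 1055 at an unadjusted p under 0.05, 11 and 17 by DESeq2), every division had to equal the labelled groups, 100 of 100 in the Yap active line (highest other 873) and 50 of 50 for the difference (highest other 1398), so these counts decide nothing. The median division called 0 genes in each case, but single divisions with many calls point to a structure among the libraries other than the labels.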
